A study of Mus musculus with 24 samples.

How the data were processed

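Total RNA and EU-labelled nascent RNA of sorted mouse testis cells were analysed in 24 libraries, 12 of each assay. Per the labels, NMRI mice were synchronised with an inhibitor of retinoic acid synthesis followed by retinoic acid, given 2 mg of EU at 24 days after birth and labelled for 3 hours, and cells were sorted by ploidy. ERCC spike-ins were added to the RNA after extraction, so they do not measure RNA per cell. Total RNA libraries were depleted of ribosomal RNA and nascent libraries were not, per the labels. The animals of the total and nascent assays carry different numbers, IND1 to IND4 and IND5 to IND8. Spermatogonia and leptotene share 2 animals in each assay, and leptotene and pachytene share 1.

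The deposited tables of total and nascent RNA hold FPKM per gene, made by the authors with STAR 2.5.2a and StringTie on mm10 per the submitters' processing notes. The StringTie version, the annotation and the use of strand are not stated there, so genes that overlap on opposite strands are uncertain. The third table holds a signal that the authors made from the nascent FPKM, as deposited, by multiplying each library by a constant of 0.441 to 5.08. How those constants were made is not stated. In all 9 libraries they equal 15.1 divided by the summed FPKM of 35 of the 177 rows named n-R5s, a set found here from the values. Those sums were 2.97 to 34.2 FPKM. The total and nascent tables have 52323 rows each, and 31272 rows are in the 5S-corrected one. Of the 21051 rows missing there, 19846 were 0 in its 9 libraries. The planned design named 12 nascent libraries, while the 5S-corrected table holds 9, without leptotene libraries 2 and 3 and pachytene library 3. The same rows summed to 0.641, 12.3 and 2.70 FPKM in those libraries.

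Rows were matched by symbol to GENCODE M21, which gave coordinates for 47531 rows (90.8%). The 92 spike-in rows were set aside from the tests. The 259 rows with several merged symbols were not, so counts of genes include those that passed the level filter. The naming rule left them out. All 15 mitochondrial rows were at 0 in every library and were not tested, so a listed 0 may also be a missing estimate. The value 1.0 was added before log2. A gene was tested with at least 1 FPKM in at least 2 libraries, which left 19202 genes in total RNA, 15839 in 5S-corrected nascent RNA and 15914 in the comparison of assays. Before 1.0 was added, the 5S-corrected values were multiplied by the same constant in all libraries, so that their mean sum equalled that of the uncorrected table. Libraries of the same animal and stage were averaged. Differences were tested two-sided with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend), with Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Total over nascent RNA was tested as the interaction of assay and stage on uncorrected FPKM, so a shift in RNA amount common to all genes is not measured. Spike-in rows are part of those FPKM, so a shift set by their share can enter.

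The nascent RNA level was the median log2 value over the 12367 genes above 0 in all 9 libraries of the 5S-corrected table, averaged per animal, with an exact permutation test over animals. Gene lists were fixed before any value was seen; 22 of 23 could be tested, and the mitochondrial list could not. They were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted by Benjamini-Hochberg over the lists. The preleptotene library was compared by list medians against 10000 random lists matched on mean expression. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

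Named genes were chosen by a rule fixed before any value was seen. It takes the 6 largest rises and 6 largest falls per contrast with adjusted p under 0.05, a mean of at least 5 FPKM in the higher stage and no overlap between the libraries of the stages. Predicted genes, clone names, pseudogenes, microRNAs, small nucleolar RNAs and 5S copies were left out of it. From each list it takes up to 4 called members with the largest change, or the 2 with the highest mean where fewer than 2 were called. Stra8, Kit, Zbtb16, Spo11, Dmc1, Sycp1, Sycp3, Prdm9, Rec8, Mki67, Ccna1, Piwil1, Pgk1, Pgk2 and Polr2a are always given. A gene that the rule selects is not reported here. The 4 genes of total over nascent RNA follow the largest changes there. Spin2e, Tsga8, H2afb3, Rn45s and n-R5s40 were chosen after their values were seen.

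Depth was read from the step between the lowest FPKM values. The implied reads, in 1e6 (M), were 7.07M to 15.8M in total RNA libraries (median 12.5M) and 5.07M to 10.1M in nascent libraries (median 6.99M), and 48.0% to 58.2% of low values lay within 0.05 of whole counts. At that depth 1 FPKM over 1500 bases is 7.61 to 23.7 reads. Genes at 1 FPKM or more numbered 11988 to 14861 in total and 8357 to 12332 in nascent libraries. Summed FPKM were 273338 to 442376 and 341597 to 807911. Spike-ins made up 2.49% to 8.19% of total and 5.01% to 76.5% of nascent FPKM.

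Pairing was checked by correlating the deviations of libraries from their stage means. The labels give the animals, so spermatogonia and leptotene of the same animal are paired by origin; across stages same-animal libraries had correlations of -0.05 to 0.08 in total and -0.18 to 0.17 in nascent RNA. Total and nascent libraries of the same title correlated at 0.122 to 0.791 in all 11 pairs, against -0.627 to 0.495 in 30 pairs of other titles. For 9 of 11 total RNA libraries the best partner had the same title. Deviations from a mean of few libraries push pairs of other titles below 0. By title, each animal number of the total assay also goes with a single number of the nascent assay. The labels do not state whether these are the same animals. The main comparison of assays took them as different animals, and an alternative fit took libraries of the same title as paired.

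The tests were tried on simulated data in which 200 genes were changed. In total RNA 2.63%, 52.5% and 95.2% of genes changed by 1, 2 and 3 log2 were recovered between spermatogonia and leptotene, of 76, 61 and 63 genes, with 11 false calls. Between leptotene and pachytene the shares were 0%, 57.4% and 93.8% of 74, 61 and 65 genes, with 5 false calls. In 5S-corrected nascent RNA they were 0%, 8.20% and 17.6% of 71, 61 and 68 genes for the first contrast and 0%, 0% and 30.5% of 72, 69 and 59 for the second, with 0 false calls. For total over nascent RNA they were 0%, 24.6% and 67.6% of 64, 65 and 71 genes (5 false calls) and 1.64%, 13.0% and 65.7% of 61, 69 and 70 (6 false calls). Of 100 random lists of 20 genes 5% had p under 0.05 by camera unchanged and 100% when shifted by 1 log2. Camera was tried there at the preset correlation only. In the simulations genes varied independently, and no error was shared by all genes of a library. The false calls and the 5% therefore do not cover errors of the 5S factors or genes that vary together. Far fewer genes were changed than the real nascent fits called, so recovery there may differ.

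Alternatives planned before any value was seen were another pseudocount, looser and stricter filters, each library as its own sample, the animal as a random or fixed replicate block, the title number as a block, eBayes without trend, a fold threshold, median-of-ratios and spike-in scaling, uncorrected nascent FPKM, and each animal left out. Others were chosen after the data were seen: scaling by every 5S row with or without n-R5s40, by the deposited 5S rows in all 12 libraries with or without leptotene library 2, only the libraries with a 5S counterpart, leptotene library 2 left out, and FPKM without spike-in rows.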

Results

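The question was whether transcription falls as male mouse germ cells enter meiosis, and whether the RNA they already hold is kept. Sorted spermatogonia, preleptotene, leptotene and pachytene spermatocytes from 24-day-old NMRI mice were compared by total RNA and by RNA labelled with EU in the animal for 3 hours. Each assay had 12 libraries: 3 of spermatogonia from 2 animals, 1 of preleptotene, 4 of leptotene from 3 animals and 4 of pachytene from 2 animals. The 5S-corrected table of nascent RNA held 9 of the 12 nascent libraries, from 2 animals each of spermatogonia, leptotene and pachytene and 1 of preleptotene. Animals were the replicates throughout, and libraries of the same animal and stage were averaged. Fold changes are given as log2 of the value plus 1, which understates the change of genes at low levels, with the standard error after the sign. Adjusted p values are two-sided, from limma with Benjamini-Hochberg adjustment. Gene coordinates are on mm10 with GENCODE M21.

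After 5S correction, which takes values relative to 5S rows, nascent RNA of the median gene was 4.37-fold lower in leptotene spermatocytes than in spermatogonia. It was 3.70-fold higher in pachytene than in leptotene. On the log2 scale the stage means were 2.36 in spermatogonia (SD 0.973), 0.23 in leptotene (SD 0.205) and 2.11 in pachytene (SD 1.0), with 2 animals each. Spermatogonia libraries lay at 3.24, 2.85 and 1.67, leptotene libraries at 0.37 and 0.08, and pachytene libraries at 1.40, 3.02 and 2.63. The single preleptotene library lay at 0.34, beside leptotene. Leptotene was lower than spermatogonia in both animals that gave both stages, by log2 differences of -1.30 and -2.96. The exact two-sided p was 0.333 for each of these differences, the smallest value that this permutation test can give with 2 animals against 2. Pachytene and spermatogonia differed by -0.24 (exact p 0.667).

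The size of the leptotene drop depended on the scaling. In uncorrected FPKM the leptotene difference was -0.30 and the pachytene difference -0.40, which is lower rather than higher than leptotene. In the 9 libraries of the 5S-corrected table they were -0.34 and -0.38. Spike-in rows are part of these FPKM, so the spike-in share of a library can move the uncorrected level. Scaled by the ERCC spike-ins, the same 9 libraries gave 0.50 for leptotene against spermatogonia and -2.64 for pachytene against leptotene, with animals spread by SDs of 2.54 in spermatogonia, 2.30 in leptotene and 1.34 in pachytene. With all 12 libraries scaled by the 5S rows behind the deposited correction, leptotene was 1.71-fold lower than spermatogonia and pachytene 1.96-fold higher than leptotene (-0.78 and 0.97). Those smaller sizes came with leptotene library 2, which held 0.490 implied reads in these rows and lay at 1.66, against -3.66 to -2.14 in the other leptotene libraries. Without it they were 3.06-fold and 3.50-fold (-1.61 and 1.81). Leaving out 1 animal moved the fall between 2.72-fold and 7.05-fold and the rise between 2.26-fold and 6.05-fold. The 5S rows behind the deposited correction summed to 25.7 and 34.2 FPKM in leptotene libraries and to 3.86, 5.55 and 16.0 in spermatogonia libraries. Pachytene libraries held 8.58, 2.97 and 6.64 FPKM. A change in 5S RNA itself between stages would therefore move the corrected level too, which was not tested. The deposited correction was recovered exactly from 35 of the 177 annotated 5S rows, which together held 3.46 to 21.1 implied reads per library. Taken as counts, they gave the 3 level differences standard errors of 0.398 to 0.487 log2. Implied reads of these rows are rough and not whole counts. Leptotene library 2 had 3 of the rows above 0 at 0.490 implied reads, and spermatogonia library 2 had 9 at 3.88. When every 5S row was summed, leptotene was still lower than spermatogonia (-1.88), but pachytene did not rise above leptotene (-0.33). That reversal rested on 1 row, n-R5s40, which lies inside Gtpbp1 on its strand. It held 23.4 of 32.5, 19.0 of 22.8 and 32.4 of 39.5 FPKM of the summed 5S rows in the 3 pachytene libraries. With every 5S row but n-R5s40 the differences were -1.97 and 1.84. In the other 6 libraries it held at most 1.41 FPKM. Whether its reads are 5S RNA or the RNA of Gtpbp1 was not tested.

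**Figure D1:**
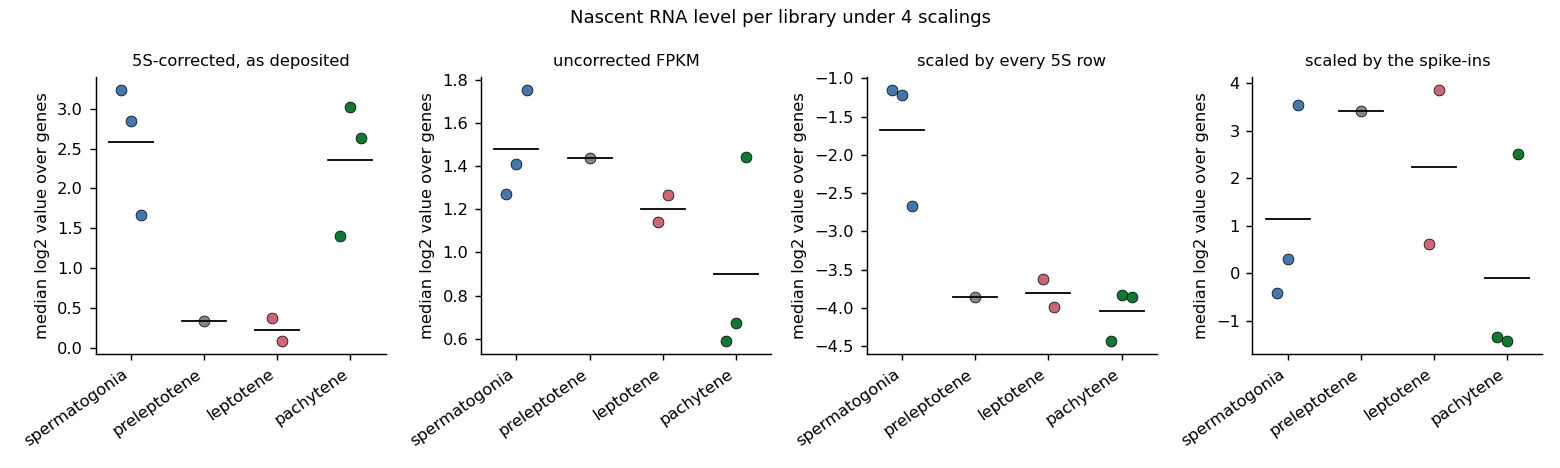
Nascent RNA level per library (dots) and mean of the libraries of a stage (lines) under 4 scalings. Stage means in the text are averaged per animal and can differ from the lines. With the 5S-corrected values leptotene lay at 0.37 and 0.08 log2. With every 5S row summed, pachytene averaged per animal was -0.33 from leptotene.

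In total RNA, Fbxo47, an F-box gene needed for meiotic prophase (chromosome 11, 97853826 to 97884154), rose from 2.09 FPKM in spermatogonia to 32.1 ± 26.7 FPKM (SD of 3 animals) in leptotene, a log2 change of 2.87 ± 0.73 (adjusted p 0.0395). The stem cell receptor gene Gfra1 (chromosome 19, 58235604 to 58455909) fell from 8.44 ± 1.49 to 1.61 ± 0.373 FPKM, by -1.86 ± 0.29 (adjusted p 0.00576). Its coreceptor Ret fell by -1.84 ± 0.31 and its target transcription factor Etv5 by -1.81 ± 0.32. Smooth muscle actin Acta2, a marker of peritubular cells (chromosome 19, 34241090 to 34255590), fell furthest, from 129 ± 69.7 to 1.14 ± 1.25 FPKM (-5.94 ± 0.50, adjusted p 0.0029). Of 19202 genes tested in 2 animals of spermatogonia and 3 of leptotene, 55 rose and 1828 fell.

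Rises by the naming rule were, after Fbxo47, the ubiquitin ligase gene Rnf44 (2.57 ± 0.45), the cell cycle phosphatase gene Cdkn3 (2.32 ± 0.44), the phosphatase activator Ptpa (2.17 ± 0.38), the X-linked Tex13c2 (2.11 ± 0.52) and the splicing regulator Ptbp1 (2.04 ± 0.53). Falls, after Acta2, were the Leydig hormone gene Insl3 (-5.63 ± 1.05) and steroid enzyme gene Hsd3b1 (-4.72 ± 0.46). They were followed by the retinal dehydrogenase gene Aldh1a1 (-4.60 ± 0.56) and the matrix genes Col4a4 (-4.35 ± 0.40) and Eln (-4.35 ± 0.42). Most of these 6 are genes of somatic testis cells. Genes of meiotic entry did not pass the test. Stra8, which starts meiosis, was at 18.1 and 22.2 FPKM (0.16 ± 0.43, adjusted p 0.859). The recombinase gene Dmc1 was at 8.91 and 37.8 FPKM (1.72 ± 0.55, adjusted p 0.0977), and the axis gene Sycp3 at 5.70 and 17.1 FPKM (1.41 ± 0.54, adjusted p 0.166). Prdm9, which places recombination sites, was at 6.89 and 19.2 FPKM (1.17 ± 0.47). Other genes always reported and not called were Sycp1 (0.71 ± 0.42), Spo11 (0.47 ± 0.44), Rec8 (-1.03 ± 0.58), Mki67 (1.30 ± 0.44), Kit (-0.92 ± 0.61), Zbtb16 (-1.45 ± 0.47), Ccna1 (1.02), Pgk2 (0.98), Piwil1 (0.91 ± 0.71) and the RNA polymerase II gene Polr2a (0.21 ± 0.31). With the animal as a fixed replicate block Dmc1 (2.02), Zbtb16 (-1.71), Rec8 (-1.70), Dazl (4.44) and Ccdc155 (2.29) were called, and Top2a (1.59), Gins1 (1.48) and Pum2 (-1.39), given below, were not. When only the 9 total RNA libraries with a counterpart in the 5S-corrected table were used, a choice made after the data were seen, Dmc1 rose by 2.65, Prdm9 by 1.94, Sycp1 by 1.33, Smc1b by 2.14 and Mki67 by 1.81.

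Gene lists were tested with camera. The adjusted p with a preset correlation of 0.01 is given first and the adjusted p with an estimated correlation second. No list in any comparison passed with an estimated correlation. That version rests on the residuals of few animals and was not tried on simulated lists. Failing it does not show that a list was unchanged. Of 17 genes of undifferentiated spermatogonia 3 fell and 14 were not called (5 fell adjusted over the list alone, camera 8.09e-05 and 0.367). The chromosome axis list (median 0.84 over 16 genes, among them Smc1b at 1.51 ± 0.42 and Syce1 at 1.20 ± 0.39) had none called, and 3 rose over the list alone (camera 5.67e-06 and 0.198). Meiotic recombination (median 0.55 over 34 genes) had none called (camera 1.99e-07 and 0.198). Meiotic entry (0.83 over 11 genes, with Dazl at 2.44 ± 1.58 and Tex101 at 1.08 ± 0.44) had none called (camera 0.000654 and 0.198). Telomere attachment (0.51 over 7 genes, with Ccdc155 at 1.79 ± 0.49) had none called and 2 risen over the list alone (camera 0.0144 and 0.198). Of 39 genes of mitotic cell cycle and replication 2 rose, Top2a by 1.46 ± 0.37 and Gins1 by 1.36 ± 0.31 (0 over the list alone, camera 0.000551 and 0.198).

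X-linked housekeeping genes had 4 of 43 fallen, Rps4x by -3.66 ± 0.44, Nono by -2.14 ± 0.44, Gnl3l by -1.44 ± 0.31 and Pgk1 by -1.36 ± 0.32 (5 over the list alone, camera 0.0126 and 0.610). Of 21 immediate-early and heat-shock genes 14 fell, with Junb at -3.61 ± 0.53, Ier2 at -2.93 ± 0.46, Ier3 at -2.92 ± 0.38 and Jun at -2.73 ± 0.49 (17 over the list alone, camera 1.5e-09 and 0.198). mRNA decay regulators had 2 of 51 fallen, Zfp36 by -2.52 ± 0.48 and Zfp36l1 by -2.22 ± 0.51 (1 over the list alone, camera 0.229). Among 36 stabilising and m6A factors Tex19.1 rose by 1.82 ± 0.44 while Pum2 fell by -1.77 ± 0.45 and Msi2 by -1.45 ± 0.36 (1 and 2 over the list alone, camera 0.559). RNA polymerase II and its factors had none of 54 called (camera 0.0766), and polymerase III and small nuclear RNAs none of 13 (median 0.43; camera 0.00111 and 0.198). Ribosomal proteins had 1 of 60 fallen (0 over the list alone, camera 0.0447 and 0.609). Replication-dependent histones had 1 of 64 risen, uncertain because the copies are alike; Hist1h2ba was at 0.41 ± 0.50 (0 over the list alone, camera 0.00224 and 0.609). Pachytene genes had none of 31 called (camera 0.000283 and 0.520), and the piRNA pathway none of 24 (camera 0.0517). Spermatid genes had none of 13 called (camera 0.761), and differentiating spermatogonia genes had 1 of 15 fallen (0 over the list alone, camera 0.756).

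Somatic markers fell beside them. Of 17 Sertoli markers 14 fell, with Clu at -3.29 ± 0.40 and Cldn11 at -2.97 ± 0.35 (15 over the list alone, camera 8.7e-12 and 0.198). Leydig markers had 7 of 10 fallen, with Cyp17a1 at -4.15 ± 0.36 (9 over the list alone, camera 6.02e-08 and 0.198). Peritubular and vascular markers had 10 of 11 fallen, with Col1a1 at -4.00 ± 0.40 (11 over the list alone, camera 1.24e-10 and 0.198). Blood and macrophage markers had 7 of 9 fallen, with Lyz2 at -3.43 ± 0.36 (9 over the list alone, camera 3.66e-08 and 0.198).

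Leptotene libraries were not alike. Across genes, leptotene library 2 had Spearman correlations of 0.874 to 0.904 with pachytene libraries and 0.528 to 0.569 with other leptotene libraries, and leptotene library 3 had 0.841 and 0.846 with leptotene libraries 1 and 4, 0.851 with preleptotene and 0.739 to 0.853 with spermatogonia; genes are not independent replicates. With the animal as a fixed replicate block, 316 genes rose and 1842 fell. Without leptotene library 2, 151 rose and 2184 fell, and with spike-in scaling 15 and 2344. The 9 libraries with a counterpart gave 1441 risen and 3501 fallen, and without the spermatogonia of animal IND3 the count was 93.

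**Figure D2:**
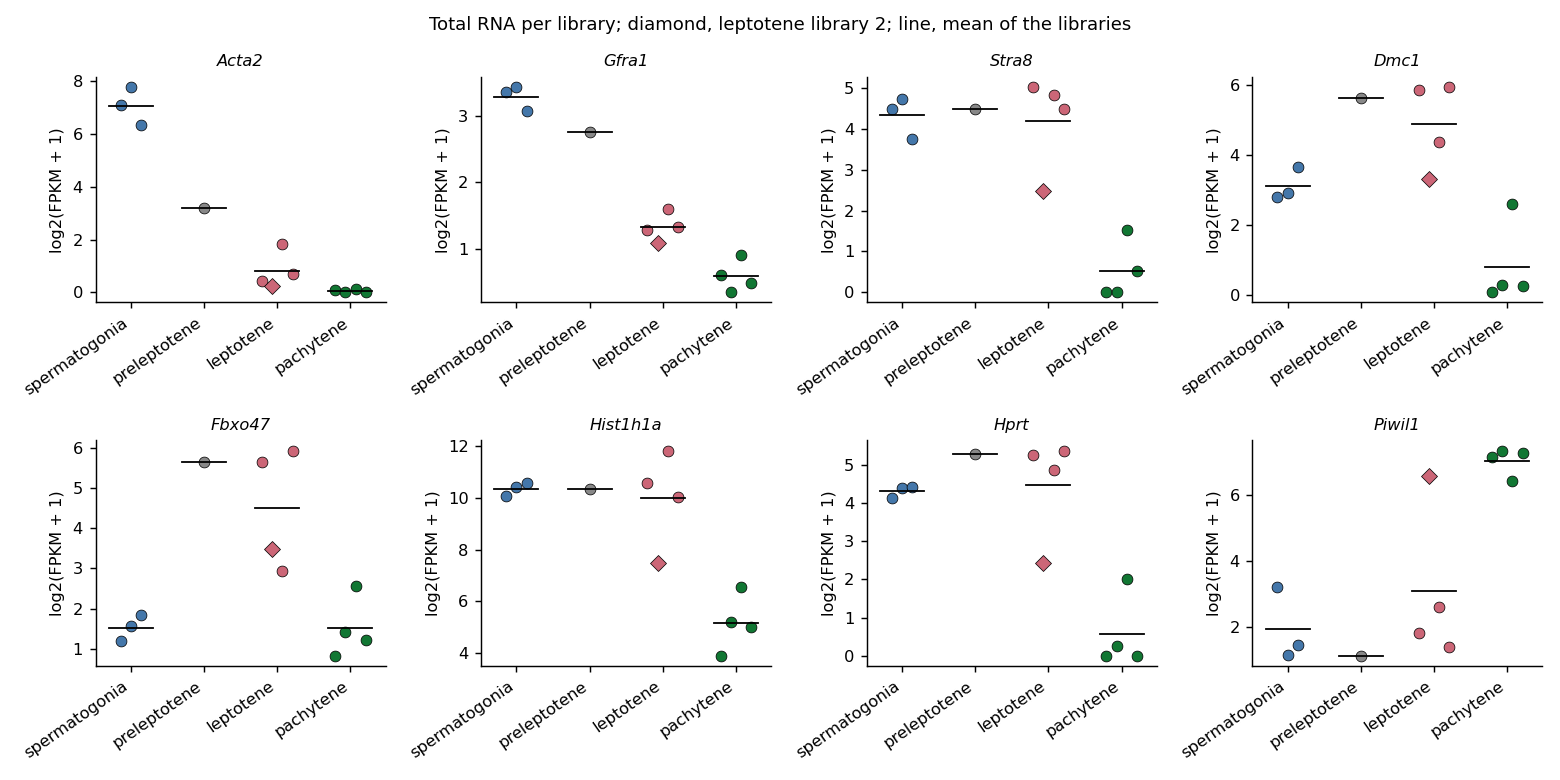
Total RNA of 8 genes per library, with a diamond for leptotene library 2 and a line for the mean of the libraries. Acta2 fell by -5.94 log2 from spermatogonia to leptotene, and Piwil1 rose by 4.32 from leptotene to pachytene.

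From leptotene to pachytene, total RNA of Stra8 (chromosome 6, 34920163 to 34939344) fell from 22.2 ± 4.73 to 0.581 ± 0.51 FPKM, by -3.84 ± 0.43 (adjusted p 0.00312). Dmc1 (chromosome 15, 79561497 to 79605109) fell from 37.8 ± 20.6 to 1.38 ± 1.66 FPKM, by -4.17 ± 0.55. Piwil1, the piRNA-binding gene of pachytene (chromosome 5, 128702524 to 128755474), rose from 18.4 ± 26.1 to 135 ± 31.3 FPKM, by 4.32 ± 0.71 (adjusted p 0.00345). The X-linked housekeeping gene Hprt (52988137 to 53021659) fell from 30.2 ± 9.96 to 0.81 ± 1.02 FPKM, by -4.14 ± 0.49. With 3 animals of leptotene and 2 of pachytene, 4303 genes rose and 3407 fell. Scaled by the spike-ins, the all-gene median moved from -0.07 to 0.62, and 7761 genes rose and 1988 fell.

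The largest rises were Morn5 (5.34 ± 0.73), the lactate dehydrogenase relative Ldhal6b (5.14 ± 0.94), the axoneme gene Rsph1 (5.01 ± 0.43), Aym1 (4.82 ± 0.63), the sperm septin Sept12 (4.80 ± 0.68) and Spata4 (4.74 ± 0.63). The largest falls were the linker histone Hist1h1a (-5.11 ± 0.68, from 1824 to 43.8 FPKM), prothymosin Ptma (-5.04 ± 0.65), Hist1h2ak (-5.00 ± 0.66) and Hist1h2ai (-4.88 ± 0.68). They were followed by the recombination gene Tex15 (-4.85 ± 0.94) and the protease gene Prss50 (-4.82 ± 0.61); the histone copies and Ptma have close relatives and are uncertain. Prdm9 (chromosome 17, 15543079 to 15564354) fell by -3.46 ± 0.47, Kit by -2.07 ± 0.61, Zbtb16 by -3.09 ± 0.47, Sycp1 by -1.65 ± 0.42 and Mki67 by -2.0 ± 0.44. Ccna1 rose by 2.36 ± 0.57 and the sperm glycolysis gene Pgk2 (chromosome 17, 40207015 to 40208640) by 4.02 ± 0.65. Spo11 (1.14 ± 0.44), Sycp3 (-0.79 ± 0.54), Rec8 (-1.03), Pgk1 (-0.64) and Polr2a (-0.29 ± 0.31) were not called. With the animal as a fixed replicate block Spo11 (2.15) and Rec8 (-2.41) were, while Sycp1 (-0.97), Terc (-2.34), Kit (-1.94) and Mki67 (-2.04) were not.

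Of 43 X-linked housekeeping genes 40 fell and 3 were not called, with Zfx at -3.47, Usp9x at -3.36 and Hcfc1 at -3.33 (41 fell over the list alone, camera 4.92e-15 and 0.476). Replication-dependent histones had 52 of 64 fallen and 4 risen, uncertain because copies are alike (52 and 5 over the list alone, camera 2.32e-15 and 0.476). Among 31 pachytene genes 27 rose, with Cetn1 at 4.47, Adam2 at 4.41 and Spata16 at 4.24 (28 risen and 1 fallen over the list alone, camera 5.84e-10 and 0.476). The piRNA pathway had 12 of 24 risen and 1 fallen, with Tdrd6 at 4.64 ± 0.82 (12 and 1 over the list alone, camera 0.00269 and 0.476). Spermatid genes had 9 of 13 risen, with Actl7b at 3.93 and Acr at 3.52 ± 0.47 (9 over the list alone, camera 0.00356 and 0.476). Meiotic recombination had 15 of 34 fallen and 2 risen (15 and 2 over the list alone, camera 0.00326 and 0.476). The chromosome axis had 4 of 16 fallen, with Smc3 at -3.20 ± 0.32 and Rad21l at -2.90 ± 0.37, and 1 risen (4 and 1 over the list alone, camera 0.0481 and 0.495). Meiotic entry had 5 of 11 fallen (5 over the list alone, camera 0.00269 and 0.476), and telomere attachment none of 7 called, with Sun1 at 1.31 ± 0.47 (camera 0.847).

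Of 15 differentiating spermatogonia genes 11 fell, with Dmrt1 at -4.03 ± 0.54 and Rhox13 at -3.85 (11 over the list alone, camera 5.77e-05 and 0.476). Undifferentiated genes had 8 of 17 fallen, with Sall4 at -3.59 ± 0.44 and Sox3 at -3.40, while Id4 rose by 3.35 ± 0.49 (10 fallen and 1 risen over the list alone, camera 0.00269 and 0.495). Mitotic cell cycle genes had 19 of 39 fallen, with Mcm4 at -3.44 ± 0.47 and E2f1 at -2.99, and 4 risen (21 and 4 over the list alone, camera 0.0023 and 0.476). RNA polymerase II and its factors had 8 of 54 fallen, with Taf7l at -4.70 ± 0.54 and Taf4b at -3.34, and 7 risen (7 and 6 over the list alone, camera 0.490). mRNA decay regulators had 10 of 51 fallen, with Patl1 at -3.38, and 6 risen, with Dis3l at 3.12 ± 0.46 (10 and 5 over the list alone, camera 0.520). Stabilising factors had 6 of 36 risen, with Ybx2 at 3.84 ± 0.59 and Ybx3 at 3.39 ± 0.42, and 5 fallen (5 and 5 over the list alone, camera 0.993). Polymerase III and small nuclear RNAs had 8 of 13 fallen, with Rmrp at -2.92 ± 0.30 and Terc at -2.41 ± 0.36, and 1 risen (9 and 1 over the list alone, camera 0.0217 and 0.476). Ribosomal proteins had 2 of 60 fallen (1 over the list alone, camera 0.520). Immediate-early genes had 12 of 21 fallen, with Jund at -3.48 ± 0.42, and 1 risen (15 and 1 over the list alone, camera 0.000622 and 0.495). Somatic markers fell for 7 of 17 Sertoli genes (camera 0.00232 and 0.495) and 4 of 11 peritubular and vascular genes (camera 0.0325 and 0.496), with as many over the lists alone. Of 10 Leydig genes 1 rose (1 over the list alone, camera 0.541), and of 9 blood and macrophage genes none was called (camera 0.293).

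With the animal as a fixed replicate block, 2591 genes rose and 1809 fell. A pseudocount of 0.1 gave 4200 risen and 4488 fallen, turning the balance between rises and falls.

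**Figure D3:**
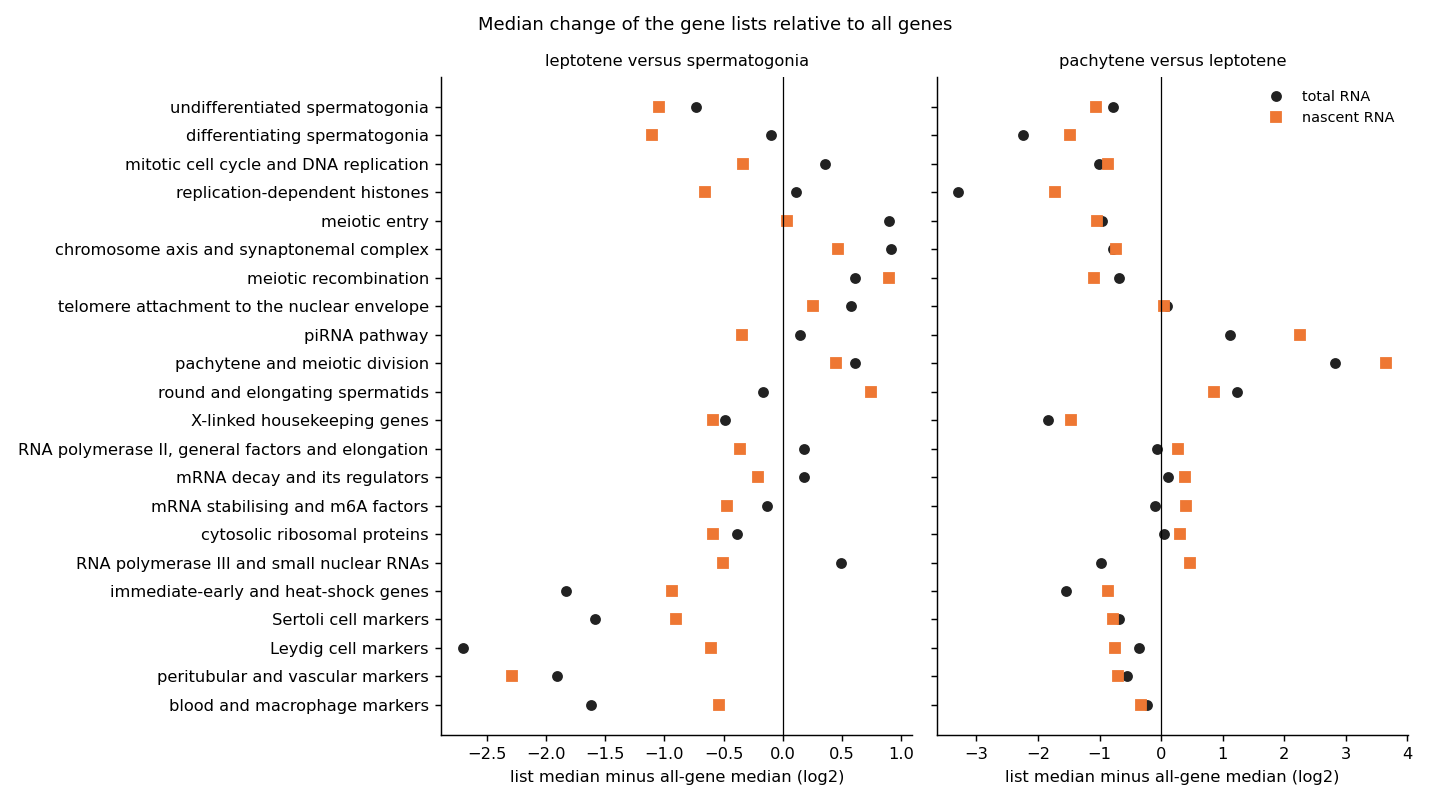
Median change of each gene list relative to all genes, total RNA as circles and nascent RNA as squares. Pachytene genes lay 2.83 log2 above all genes in total RNA and 3.66 in nascent RNA from leptotene to pachytene.

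In 5S-corrected nascent RNA, Stra8 fell from 44.0 ± 36.1 in spermatogonia to 4.53 ± 1.66 in leptotene, by -2.58 ± 0.74 (adjusted p 0.00517, 2 animals of each). Gfra1 fell by -3.20 ± 0.62 (adjusted p 2.31e-05), Ret by -2.83 ± 0.57, Kit by -2.62 ± 0.67 and Zbtb16 by -3.39 ± 0.78. Fbxo47 rose against the common fall, from 4.66 to 37.4 (2.67 ± 0.83, adjusted p 0.00989), as did the recombination genes Rad51ap2 (2.38 ± 0.82) and Meiob (2.15 ± 0.78) and the GTPase regulator Tbc1d10c (1.76 ± 0.66). Of 15839 genes tested, 43 rose and 4356 fell, with an all-gene median of -1.0. Median-of-ratios scaling, which removes the common shift, moved that median to -0.06 and gave 2526 risen and 3287 fallen.

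Falls by the naming rule were the retinoic acid hydroxylase gene Cyp26b1 (-6.28 ± 0.90), Fgl2 (-6.25 ± 0.86), Plpp3 (-5.42) and the muscle gene Myl9 (-5.10). Acta2 was at 338, 237 and 52.4 in the spermatogonia libraries and was listed at 0 in both leptotene libraries; Rec8 was at 4.89, 3.03 and 4.97 and was also listed at 0 in leptotene. Pgk1 fell by -1.25 ± 0.43. Dmc1 lay at 22.7 and 40.9 (0.83 ± 0.94, adjusted p 0.512). Also not called were Prdm9 (-0.02 ± 0.86), Spo11 (0.73 ± 0.70), Sycp1 (-0.50), Sycp3 (-1.05 ± 0.82), Mki67 (-0.43), Piwil1 (-0.98) and Polr2a (-1.91 ± 1.12). Relative to other genes some of these rose. With median-of-ratios scaling Prdm9 rose by 1.90, Mki67 by 1.53 and Sycp1 by 1.28, and in uncorrected FPKM of the same 9 libraries Dmc1 rose by 2.56, Spo11 by 2.18 and Prdm9 by 1.69.

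List medians are given relative to the all-gene median. Meiotic recombination lay 0.90 above it, with 1 of 33 genes risen and 3 fallen, among them Tex15 at -3.24 ± 0.96 (1 and 3 over the list alone, camera 8.83e-06 and 0.834). The chromosome axis lay 0.47 above, with 1 of 16 fallen (1 over the list alone, camera 0.044 and 0.834), and spermatid genes 0.75 above with none of 11 called (camera 0.0168 and 0.834). Undifferentiated genes lay at -1.05, with 10 of 15 fallen (12 over the list alone, camera 0.0133 and 0.834), and differentiating genes at -1.10, with 10 of 15 fallen (14 over the list alone, camera 4.81e-05 and 0.834). Immediate-early genes lay at -0.94, with 17 of 20 fallen (17 over the list alone, camera 0.000496 and 0.834). X-linked housekeeping genes lay at -0.59, with 27 of 43 fallen, among them Rbbp7 at -3.20 ± 0.83 and Magt1 at -3.07 ± 0.64 (30 over the list alone, camera 4.81e-05 and 0.834). Ribosomal proteins lay at -0.59 too, with 28 of 54 fallen, such as Rps15 at -3.21 ± 0.86 (38 over the list alone, camera 0.000496 and 0.834). Replication-dependent histones lay at -0.66, with 16 of 65 fallen, uncertain for alike copies (15 over the list alone, camera 0.0106 and 0.834); in uncorrected FPKM 2 rose and none fell.

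Stabilising factors lay at -0.47, with 13 of 36 fallen (13 over the list alone, camera 0.0382 and 0.834). mRNA decay regulators had 6 of 50 fallen, among them Zfp36l1 at -4.16 ± 0.71 (5 over the list alone, camera 0.0745). RNA polymerase II and its factors had 9 of 50 fallen, among them Gtf2a1 at -3.37 ± 1.04 (8 over the list alone, camera 0.056). Mitotic cell cycle genes had 7 of 37 fallen, among them Ccnd1 at -3.53 ± 0.68 (6 over the list alone, camera 0.105), and their median of -1.33 became 0.02 in uncorrected FPKM. The piRNA pathway had 6 of 22 fallen (6 over the list alone, camera 0.229), pachytene genes 2 of 31 (0 over the list alone, camera 0.0745) and polymerase III and small nuclear RNAs 1 of 12 (0 over the list alone, camera 0.598). Meiotic entry had 2 of 11 fallen (2 over the list alone, camera 0.987), and telomere attachment 1 of 7 (1 over the list alone, camera 0.126). Somatic markers fell for 13 of 15 Sertoli genes (camera 0.00161 and 0.834), 8 of 9 Leydig genes (camera 0.0111 and 0.834), all 10 peritubular and vascular genes (camera 8.83e-06 and 0.834) and all 6 blood genes (camera 0.0745), or 14, 8, 10 and 6 over the lists alone.

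No gene passed with the animal as a fixed replicate block (3902 at unadjusted p under 0.05 by limma) or with spike-in scaling (526 at unadjusted p). Removing either leptotene animal left 35 or 37 genes.

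From leptotene to pachytene nascent Piwil1 rose from 0.176 to 253 ± 149 after 5S correction, by 6.81 ± 0.79 (adjusted p 3.77e-15, 2 animals of each). Tdrd6 of the same pathway rose by 7.04 ± 0.82 and Pgk2 by 4.33 ± 0.63. Dmc1 fell against the common rise, from 40.9 to 2.37 (-3.33 ± 0.94, adjusted p 0.00221), and so did Prdm9 (-2.91 ± 0.86) and Hprt (-2.19 ± 0.80, adjusted p 0.0221). In all 5172 genes rose and 212 fell, with an all-gene median of 0.86. That balance followed the scaling: median-of-ratios scaling gave 4670 risen and 3710 fallen with a median of 0.00, uncorrected FPKM of the same 9 libraries 3569 and 4777 with -0.24, uncorrected FPKM of all 12 libraries 2590 and 2514 with -0.27, and scaling by every 5S row 1462 and 960 with -0.10.

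The largest rises were Cdc42ep3 (7.35 ± 0.93), Eid3 (7.30 ± 0.86), Morc2b (7.20 ± 0.83), Csl (7.19), the poly(A)-binding gene Pabpc2 (7.18) and the glycerol kinase gene Gk2 (7.15). The largest falls were Fbxo47 (-3.54 ± 0.83), Rad51ap2 (-3.37 ± 0.82) and Dmc1, then the X-linked Jade3 (-3.29), Tex16 (-3.24) and Pet2 (-3.16). Spo11 rose by 2.30 ± 0.70 with 5S correction but lay at -0.48 with spike-in scaling. Ccna1 was listed at 0 in both leptotene libraries and at 13.9, 10.6 and 8.79 in pachytene. Stra8 (-1.51 ± 0.74), Kit (-0.86), Zbtb16 (-1.07), Mki67 (-0.70), Sycp3 (0.74 ± 0.82), Rec8 (0.03) and Polr2a (2.27 ± 1.12) were not called. In uncorrected FPKM Stra8 fell by -2.91, Kit by -2.40, Zbtb16 by -2.58, Mki67 by -2.19 and Sycp3 by -1.15.

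Relative to the all-gene median, pachytene genes lay at 3.66, with 28 of 31 risen, such as Ybx3 at 6.63 ± 0.91 and Cetn1 at 6.28 (28 over the list alone, camera 2.58e-14 and 0.835). The piRNA pathway lay at 2.25, with 19 of 22 risen (19 over the list alone, camera 8.56e-06 and 0.835), and spermatid genes at 0.86, with 9 of 11 risen (9 over the list alone, camera 0.0264 and 0.835). X-linked housekeeping genes lay at -1.47, with 6 of 43 fallen and none risen, such as Zfx at -2.64 ± 0.85 and Kdm6a at -2.45 ± 0.74 (2 over the list alone, camera 4.39e-16 and 0.835). Replication-dependent histones lay at -1.72, with 7 of 65 risen and 3 fallen (6 and 1 over the list alone, camera 1.2e-15 and 0.835); in uncorrected FPKM 51 fell and 5 rose. Meiotic recombination lay at -1.09, with 4 of 33 risen, such as Mlh3 at 4.04 ± 0.80 and Swi5 at 3.35 ± 0.65, and 2 fallen (4 and 2 over the list alone, camera 1.88e-05 and 0.835). Meiotic entry lay at -1.05, with 2 of 11 fallen (2 over the list alone, camera 0.00211 and 0.835), and the chromosome axis at -0.74, with 2 of 16 fallen (2 over the list alone, camera 0.00194 and 0.835). Differentiating genes lay at -1.47, with 3 of 15 risen, such as Dmrtb1 at 5.03 ± 0.80, and 2 fallen (3 and 2 over the list alone, camera 0.000594 and 0.835). Undifferentiated genes lay at -1.05, with 1 of 15 risen, Id4 at 5.30 ± 0.77 (1 over the list alone, camera 0.00325 and 0.835).

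Mitotic cell cycle genes lay at -0.86, with 5 of 37 risen and 1 fallen (4 and 0 over the list alone, camera 0.0149 and 0.835); in uncorrected FPKM 16 fell and none rose. RNA polymerase II and its factors had 11 of 50 risen, such as Gtf2a1 at 4.71 ± 1.04 and the bromodomain gene Brdt at 3.62 ± 0.83, and 3 fallen (7 and 1 over the list alone, camera 0.903); their median turned from 1.15 to -0.44 in uncorrected FPKM. mRNA decay regulators had 15 of 50 risen and 1 fallen (15 and 1 over the list alone, camera 0.657), with a median of 1.25 that became -0.37 in uncorrected FPKM. Stabilising factors had 10 of 36 risen and 2 fallen (10 and 2 over the list alone, camera 0.903), with 1.26 becoming -0.34. Ribosomal proteins had 13 of 54 risen (9 over the list alone, camera 0.254), with 1.18 becoming -0.19. Polymerase III and small nuclear RNAs had 3 of 12 risen, such as Rnu2-10 at 4.05 ± 1.05 (2 over the list alone, camera 0.626), with 1.33 becoming -0.73. Telomere attachment had none of 7 called (camera 0.997). Immediate-early genes had 2 of 20 risen (1 over the list alone, camera 0.0105 and 0.835). Somatic lists had 1 gene risen, of 9 Leydig genes (1 over the list alone, camera 0.174), and none called of 15 Sertoli (camera 0.0264 and 0.835), 10 peritubular and vascular (camera 0.0681) or 6 blood genes (camera 0.657).

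The animal as a fixed replicate block could not be used for this contrast. In the 5S-corrected libraries no animal gave both leptotene and pachytene, so such a fit cannot separate stage from animal. With spike-in scaling no gene passed (720 at unadjusted p under 0.05 by limma). Scaling by the same 5S rows in all 12 libraries, among them leptotene library 2 with 0.490 implied reads in those rows, left 583 rises and no falls.

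Between spermatogonia and leptotene no single gene was called as changed in total RNA relative to nascent RNA. Both assays entered as uncorrected FPKM, so a shift in RNA amount common to all genes was not measured. The test therefore cannot say whether RNA was kept across most genes while transcription fell. Spike-in rows were part of those FPKM, at 2.49% to 8.19% in total and 5.01% to 76.5% in nascent libraries. A shift set by the spike-in share can enter the test. Stra8 had a change in total over nascent RNA of 1.12 ± 0.71, Sycp3 of 0.71 ± 0.65, Spo11 of -1.12 ± 0.68, Prdm9 of 0.09 ± 0.75, Dmc1 of 0.01 ± 0.95 and Polr2a of 0.43 ± 0.48 (adjusted p 0.999 each, uncorrected FPKM, 2 and 3 animals per assay). No gene of 15914 passed limma with Benjamini-Hochberg adjustment, and 444 had an unadjusted p under 0.05. On simulated data the test recovered 24.6% of genes changed by 2 log2. Immediate-early genes lay -0.63 from the all-gene median (camera 6.02e-05 and 0.713), Leydig markers -1.07 (camera 1.44e-05 and 0.681), blood markers -0.56 (camera 0.00139 and 0.700) and Sertoli markers -0.28 (camera 0.0254 and 0.961). Meiotic entry lay at 0.61 (camera 0.0268 and 0.713), differentiating genes at 0.42 (camera 0.0238 and 0.883) and spermatid genes at -0.22 (camera 0.0268 and 0.883). The other 15 lists did not pass camera. Of 4304 genes that fell in 5S-corrected nascent RNA and were tested in total RNA, 1315 fell in total RNA, 4 rose and 2985 were not called. The 5S-corrected values keep a shift common to all genes (median -1.02), while total RNA in FPKM does not (median -0.08). The numbers of animals differ too, so genes not called in total RNA need not be genes whose RNA was kept. Across 15441 genes, which are not independent replicates, the changes in the 2 assays had a Spearman correlation of 0.579. With 5S-corrected nascent values the all-gene median was 0.79 and 6 genes rose.

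From leptotene to pachytene, 4 genes changed in total over nascent RNA, 1 risen and 3 fallen. Without leptotene library 2, left out after the data were seen, 203 rose and 40 fell. The small GTPase partner gene Rundc3b rose by 3.47 ± 0.50 (adjusted p 0.0363; chromosome 5, 8490334 to 8622952). The ubiquitin ligase subunit gene Rnf7 fell by -5.33 ± 0.49 (adjusted p 0.000457; chromosome 9, 96470937 to 96478675): in pachytene it was at 0.19 to 0.308 FPKM in total RNA and at 16.3 to 35.6 FPKM in nascent RNA. Cdc42ep4 fell by -4.98 ± 0.63 and the recycling gene Rab11fip2 by -3.88 ± 0.59. At unadjusted p under 0.05 there were 1074 genes. Immediate-early genes lay at -1.15 from the all-gene median (camera 4.66e-08 and 0.478), histones at -0.86 (camera 4.66e-08 and 0.492), Sertoli markers at -0.75 (camera 4.72e-08 and 0.478) and X-linked housekeeping genes at -0.45 (camera 3.19e-05 and 0.492). Differentiating genes lay at -0.82 (camera 9.79e-05 and 0.478), undifferentiated genes at -0.66 (camera 0.00155 and 0.492) and the chromosome axis at 0.53 (camera 0.00475 and 0.478). Peritubular markers lay at -0.57 (camera 0.00142 and 0.492), blood markers at -0.52 (camera 0.00475 and 0.478), Leydig markers at -0.66 (camera 0.0393 and 0.492) and polymerase III and small nuclear RNAs at -0.45 (camera 0.0262 and 0.492). The other 11 lists did not pass. Of 5101 genes that rose in 5S-corrected nascent RNA, 3355 rose in total RNA, 30 fell and 1716 were not called. The scalings again differ, with all-gene medians of 0.89 in nascent and -0.01 in total RNA, so these counts do not compare like with like. The Spearman correlation across genes was 0.827. Using only the libraries with a 5S counterpart gave 290 risen and 118 fallen, and 5S-corrected nascent values gave 1 and 166. With total and nascent libraries of the same title paired in a replicate block, 8 genes changed, with Rnf7 and Cdc42ep4 among them but not Rundc3b or Rab11fip2. With the animal as a fixed replicate block 4 genes passed, none of them one of these 4, which kept their directions (3.49, -5.26, -4.64 and -4.56). Of 10 fits that each left out 1 animal, 4 kept 1 of the 4 genes, 4 kept 2 and 2 kept all 4.

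The preleptotene library had no replicate, so its lists were set against 10000 random lists of the same size. Random lists measure the spread between genes and not between libraries, so a difference of stage cannot be separated from one of this library. In total RNA the chromosome axis list lay 1.15 above spermatogonia, meiotic entry 0.75, meiotic recombination 0.68 and telomere attachment 0.61, all outside 95% of the random lists. Histones lay at 0.43, immediate-early genes at -1.73, ribosomal proteins at -0.51, Sertoli markers at -1.45, Leydig markers at -2.11, peritubular and vascular markers at -1.91 and blood markers at -1.32, also outside. Against leptotene, undifferentiated genes lay at 0.52, X-linked housekeeping genes at 0.31 and pachytene genes at -0.51, outside as well. The leptotene means in both assays include leptotene library 2, which lay close to pachytene. The comparison was not repeated without it, so these differences may partly be those of that library. Of the markers of other cells, the peritubular and vascular list lay at 0.98, the Leydig list at 0.66 and the blood list at 0.31, all outside, and the Sertoli list at 0.22, not outside. Immediate-early genes lay at 0.32, outside. In nascent FPKM, telomere attachment lay 1.43 above spermatogonia, the chromosome axis 1.27 and meiotic recombination 1.17, while Sertoli markers lay at -1.42, Leydig markers at -1.53, peritubular and vascular markers at -2.19 and blood markers at -1.59, all outside. Against leptotene the 3 meiotic lists lay at 0.68, 0.60 and 0.57, peritubular and vascular markers at 0.72 and immediate-early genes at 0.51, outside as well. In total RNA 13 of 22 lists were outside against spermatogonia and 10 against leptotene; in nascent FPKM 14 and 13 were.

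**Figure D4:**
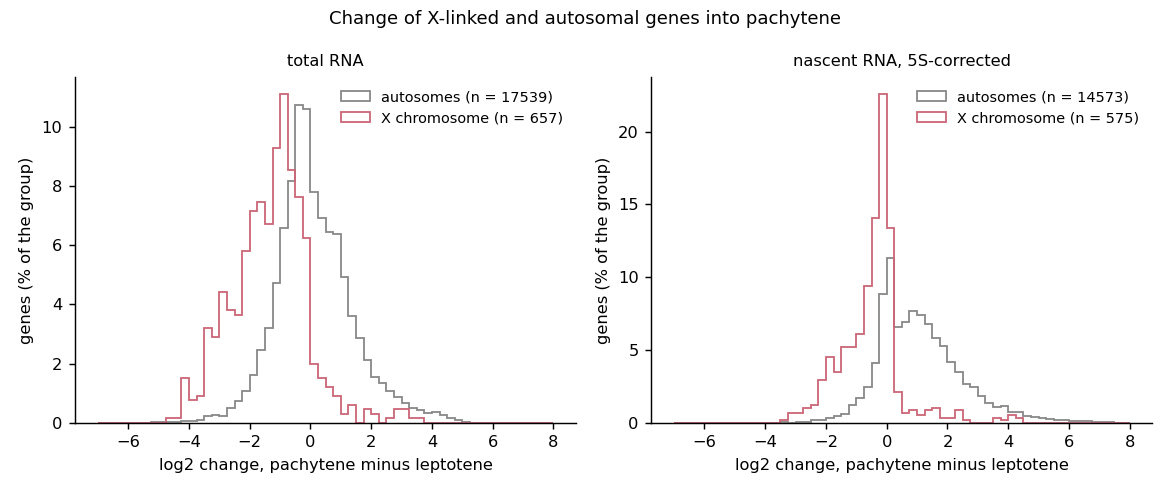
Change from leptotene to pachytene of autosomal and X-linked genes in total and nascent RNA. The X-linked median was -1.21 log2 in total RNA and -0.33 in nascent RNA.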

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

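The tests of explanations in this part were chosen after the results were seen, except the regroupings of libraries, which were planned. Within a stage of 4 libraries, Dixon's test marks a library that stands apart, and by chance it marks about 1 in 20 groups. Of 127 genes, leptotene library 2 stood apart for 25 in total RNA and 27 in nascent RNA, and pachytene library 3 for 22 and 18. Leptotene library 3 stood apart for 3 and 7 genes, pachytene library 2 for 3 and 2 and pachytene library 1 for 2 and 1. In nascent RNA leptotene library 4 did so for 2 genes and leptotene library 1 for 1. Of 22 list medians, leptotene library 2 stood apart for 3 in total and 2 in nascent RNA, pachytene library 3 for 5 in total RNA, and in nascent RNA pachytene library 4 for 2 and pachytene library 2 for 1. The spike-in share of pachytene library 4 in total RNA, 2.49%, stood below the other pachytene libraries. Between leptotene and pachytene the interaction test found different changes in total and nascent RNA for Rundc3b (3.47), Rnf7 (-5.33), Cdc42ep4 (-4.98) and Rab11fip2 (-3.88).

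The nascent level, low in leptotene and higher in pachytene, was weighed against the choice of 5S rows. With every 5S row summed the pachytene difference was -0.33 instead of 1.89, while the leptotene fall was kept at -1.88. That reversal rested on n-R5s40, a row inside Gtpbp1 on its strand that held 19.0 to 32.4 of 22.8 to 39.5 FPKM in the pachytene libraries. Without it the difference was 1.84, so the rise to pachytene could come from the choice of 5S rows only where n-R5s40 counts as 5S RNA. Scaling to spike-ins gave 0.50 for leptotene against spermatogonia with animal SDs of 2.30 and 2.54, and on this test a scaling effect and a true fall cannot be told apart. A change in 5S RNA between stages would also move the corrected level and was not tested. A real drop in transcription at leptotene stays open and was not tested separately.

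Leptotene library 2 lay close to pachytene. Its pachytene share was read from 418 genes high in leptotene libraries 1 and 4. A pachytene library under the wrong label should reach the share of the 4 pachytene libraries, 0.921 to 1.04, and this one fell short at 0.860. Pachytene library 3, at 0.921, itself lay below the others, at 1.02 to 1.04. With so few libraries and a rule set after the result, a swapped label could not be excluded. Leptotene and pachytene cells sorted together would give similar shares from both sides, and 1098 genes high in pachytene gave 0.812 in total RNA. A mixture could give this, but similar shares are not particular to one, so the test cannot tell it from cells of an intermediate stage. In nascent RNA the share from genes high in leptotene was 0.774, against 0.904 to 1.04 in pachytene libraries. The share from genes high in pachytene was 0.430, against 0.441 to 1.96, which does not separate it from pachytene library 3. Cells of a stage between leptotene and pachytene stay a biological alternative that was not tested.

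Somatic markers fell from spermatogonia to leptotene. In total RNA 38 of 47 members of the 4 somatic lists fell and none rose, and in uncorrected nascent FPKM 35 of 39, as somatic cells among the sorted spermatogonia could give. A shift of all genes from library depth or composition is unlikely, since the all-gene median was -0.0692 against -1.89 for these lists. Expression of these genes in spermatogonia stays open and was not tested.

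Libraries were also regrouped in all 35 ways. For total RNA of leptotene and spermatogonia 2 of 35 groupings gave as many genes, 3407 in the real one and 3501 with leptotene library 3 placed among all 3 spermatogonia libraries, so by count a chance arrangement could not be excluded. That grouping differs from the real one by 1 library and keeps the spermatogonia together. Why it gave as many genes was not tested. The other 33 gave at most 32 genes. For total RNA of pachytene and leptotene 1 of 35 did, the real one, with 8884 genes against at most 6582. For total over nascent RNA it was 1 of 35 in both contrasts, with 4 genes against 2 and 13 against 4. The regroupings took each library as its own sample, and libraries of the same animal are not independent. Per animal the counts were 1883 and 7710 in total RNA and 0 and 4 for total over nascent RNA.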

How the results depend on the processing

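Changes in total RNA between spermatogonia and leptotene numbered 1883. They were 2904 without the level filter, 579 at 5 FPKM, 3407 with each library as its own sample and 3397 with the animal as a random replicate block. Libraries with a 5S counterpart gave 4942, or 6800 each as its own sample. Leaving out an animal gave 93 (spermatogonia IND3) to 2899 (leptotene IND4), with 1029 without leptotene IND3. Leaving out leptotene library 2 gave 2335, with rises from 55 to 151. Between leptotene and pachytene 7710 genes changed. A pseudocount of 0.1 gave 8688 with more falls than rises, the 5 FPKM filter 4669 and the fixed animal block 4400. Leaving out an animal gave 2649 (pachytene IND2) to 9096, with 3073 without pachytene IND4.

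In nascent RNA 4399 genes changed between spermatogonia and leptotene. None did without the level filter (0), with the fixed animal block (0), with spike-in scaling (0) or with the same 9 libraries scaled so (0). Other counts were 2523 at 5 FPKM, 7456 with each library as its own sample, 8644 with the random animal block, 2151 without trend, 5849 in uncorrected FPKM of the same 9 libraries, 1735 in that of all 12 and 149 with all 12 libraries scaled by the deposited 5S rows. Leaving out an animal gave 35 (leptotene IND7) to 5453, with 37 without leptotene IND5 and 150 without spermatogonia IND7. Between leptotene and pachytene 5384 changed. Both spike-in scalings gave 0, median-of-ratios 8380, every 5S row 2422 and 12 libraries by the deposited 5S rows 583. The fixed animal block gives no usable count here, since no animal of the 5S-corrected libraries gave both stages. Uncorrected FPKM of the same 9 libraries gave 8346 with more falls than rises. Leaving out an animal gave 1131 (pachytene IND8) to 4470, with 1450 and 1373 without leptotene IND5 and IND7. Where a stage was left with 1 animal, it was assumed to vary like the other stages.

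Total over nascent RNA had 0 genes changed between spermatogonia and leptotene, 63 without the level filter, 4 with each library as its own sample, 4 with the random animal block, 1 with the title number as a replicate block and 6 with 5S-corrected values. Libraries with a 5S counterpart gave 10, or 13 without spike-in rows, and leaving out an animal 0 to 1. Between leptotene and pachytene 4 changed, mostly falls. Rises were the majority among 22 without the level filter, 13 with each library as its own sample, 13 with the random animal block, 408 with the 5S counterparts, 1084 with the same libraries and spike-in rows removed and 243 without leptotene library 2. Corrected values gave 167 and the paired replicate block of same titles 8. Leaving out an animal gave 1 (pachytene nascent IND8) to 57 (leptotene total IND1), the latter mostly rises.

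The nascent level from spermatogonia to leptotene, -2.13, became -0.30 in uncorrected FPKM, -0.34 in the same 9 libraries, 0.50 and -0.17 with spike-ins in 9 and 12 libraries and -0.78 with the deposited 5S rows in 12, or -1.61 without leptotene library 2, which held 0.490 implied reads there. From leptotene to pachytene 1.89 became -0.40, -0.38, -2.64 and -2.08 in the first 4 of these and -0.33 with every 5S row. From spermatogonia to pachytene -0.24 became -2.15 and -2.25 with spike-ins and -2.21 with every 5S row. Leaving out an animal gave -2.82 to -1.44, 1.18 to 2.60 and -0.95 to 0.47. Paired by animal, the 2 animals with both stages gave -1.30 and -2.96 and were not tested further. Camera with an estimated correlation left 0 lists in each of the 6 comparisons, of 16, 15, 13, 13, 7 and 11. It rests on few animals and was not tried on simulated lists, so this does not show that the lists were unchanged.

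Of named genes, nascent Spo11 from leptotene to pachytene turned to -0.48 and -1.38 with spike-in scaling of 12 and 9 libraries, Rnu2-10 to -0.69 and -0.22 and Brdt to -0.17 with 9. Sycp3 was called at -0.86 with median-of-ratios, -1.15 in uncorrected FPKM and -1.20 in the same 9 libraries. From spermatogonia to leptotene nascent Sycp1 was called at 1.28, Prdm9 at 1.90 and Mki67 at 1.53 with median-of-ratios, and Prdm9 at 1.69 in FPKM of the same 9 libraries. Calls kept with the fixed animal block were 32 of 35 and 46 of 50 genes in total RNA. In nascent RNA of leptotene against spermatogonia they were 0 of 24, and for total over nascent RNA 0 of 4. Directions were kept in these comparisons. The block added calls for 5 of 18 uncalled genes in total RNA of leptotene and 2 of 6 of pachytene. For nascent pachytene against leptotene it could not separate stage from animal, as no animal gave both stages in the 5S-corrected libraries. It remains among the 16 nascent alternatives counted next. Counts stayed within 1.5 times in 8 and 11 of 14 alternatives in total RNA, 6 and 9 of 16 in nascent RNA and 9 and 8 of 16 for total over nascent RNA, and the 3 levels stayed within their spread in 6, 6 and 8 of 11, with every 5S row but n-R5s40 giving -1.97, 1.84 and -0.13. The cause of these differences was not tested. Read depth limits low genes most, and the 5S rows behind the correction held 3.46 to 21.1 implied reads.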

Other observations

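Most X-linked genes fell in total RNA between leptotene and pachytene, though the X was not tested against the autosomes. In total RNA 396 of 657 X-linked genes fell (60.3%), 24 rose and the median change was -1.21 log2, while on single autosomes 13.8% to 21% of genes fell and medians were -0.16 to 0.07. In 5S-corrected nascent RNA 75 of 575 X-linked genes fell and 23 rose, with a median of -0.33 against 0.76 to 1.05 on autosomes, where 0.278% to 1.89% of genes fell. From spermatogonia to leptotene 118 of its genes fell in total RNA and 3 rose (18.0%, median -0.40), while on single autosomes 6.50% to 13.3% fell with medians of -0.18 to 0.01. In nascent RNA 308 of 575 fell (53.6%, median -1.31), against 21.8% to 34.3% with medians of -1.12 to -0.87 on single autosomes. Among the 24 X-linked genes that rose in total RNA by pachytene were 8 of the Spin2 family, such as Spin2e at 3.44, besides Tsga8 at 1.90 and the histone variant H2afb3 at 1.27. The Spin2 genes are near copies, so which of them rose is uncertain.

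The 45S ribosomal precursor Rn45s made up 11.7% to 16.7% of total RNA FPKM in spermatogonia, preleptotene and 3 leptotene libraries, 5.74% in leptotene library 2 and 1.65% to 3.10% in pachytene libraries. Total libraries were depleted of ribosomal RNA, so these shares are what was left after depletion. Some histone genes rose in nascent RNA by pachytene while most of the family did not: Hist2h2be by 5.54 ± 0.75, Hist3h2a by 4.99 ± 0.90 and the testis linker histone Hist1h1t by 4.42 ± 1.06. Id4 of the undifferentiated list rose by pachytene in both assays, by 3.35 ± 0.49 in total RNA and 5.30 ± 0.77 in nascent RNA, while Sall4 of the same list fell by -3.59 ± 0.44 in total RNA. The 5S row n-R5s40 on chromosome 15 (79692502 to 79692625), inside Gtpbp1 and on its strand, was at 19.0 to 32.4 FPKM in the 3 pachytene libraries of the 5S-corrected table. It was at 7.94 in pachytene library 3, 4.38 in leptotene library 2 and at most 1.41 in the other libraries.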
